A study of Mus musculus with 20 samples.

How the data were processed

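RNA was measured on mouse expression arrays with 1 array per sample, 20 in all: 12 of fetal liver CFU-E cells with Epo and 8 without, at the times given with the results. Per the labels' protocols, cells were sorted magnetically and RNA was extracted with a column kit. The deposited values are on a log2 scale, as their range of 1.37 to 14.6 shows. How probe intensities were summarised and scaled by the authors, and with which software, is not given in the sources used here. Depth has no counterpart on arrays, and the number of arrays limits the precision.

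The value table held 45101 probe sets. Of these, 34958 named 1 gene in the platform annotation, 932 named several and 9211 were unnamed here; 64 were control probe sets, used for array quality only. For 34754 of the probe sets with 1 gene the gene was found in a reference gene table of assembly GRCm38.p6, used for names only, and no symbol changed. Each of 18194 genes was represented by the probe set with the highest mean over all 20 arrays. For 9011 genes there was more than 1 probe set. Among the genes called at least 2-fold between the series, 698 had another probe set, and 1092 of 1322 such probe sets (82.6%) moved in the same direction. No filter on dim genes was used. No coordinates were used.

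Groups, times, tests, gene lists and alternatives were chosen before the data were examined, unless stated otherwise. The Epo effect at 1 to 7 h was fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend) on 14 arrays with time as a block. The change of the Epo effect was the slope of the 7 matched differences on time. Time without Epo was the slope over 8 arrays, and the late comparison set the mean of 14, 19 and 24 h against that of 1 to 8 h. Matched differences per hour were counted at a log2 difference of at least 1, without a test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. In the text, "adjusted over the list alone" means adjustment over the members of a list. The 31 gene lists were tested with camera at a correlation of 0.01 between genes and adjusted over the lists; 49 list entries matched no gene tested. With an estimated correlation, the heme synthesis call without Epo remained and no other list call did. Control transcripts were compared by an exact permutation test. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

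Named genes followed a rule: per comparison, from the 10 largest rises and 10 largest falls among called genes (for the Epo effect, of the same sign in all 7 pairs), and from the up to 4 members of each list with the largest change. Cish, Socs3, Epor, Jak2, Stat5a, Stat5b and Pim1 were always named. Genes known only by a clone or predicted name were left unnamed. A gene named outside this rule is said to be so.

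The fits were tested on simulated data of 18194 genes, of which 200 changed by a known size. For the Epo effect, 100.0% of genes changed by 2 on the log2 scale were called in the right direction, 94.0% of those changed by 1 and 57.6% of those changed by 0.5, and 8 unchanged genes were called. For the change of the Epo effect, with sizes over the whole span, the shares were 83.6%, 14.9% and 0.0%, with 1 unchanged gene called. For time without Epo they were 98.5%, 65.7% and 13.6%, with 6, and for the late comparison 98.5%, 91.0% and 28.8%, with 9. The simulated noise was independent between arrays and between genes, with no difference between the series apart from the changes put in. False calls from such a difference or from a drift over time were thus not measured. The shares may differ where more genes change.

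Alternatives were quantile normalization, centring each array on its median, the brighter genes only, the mean of all probe sets, probe sets without cross-hybridising suffixes, other variance models, each time left out, other uses of the 0 h arrays, other time scales and, for the lists, an estimated correlation. Added after the data were seen were the subtraction of each gene's 0 h difference between the series, without and with a linear drift of the matched differences, 0 h as a further matched difference in the slope, and readouts without the arrays of 2 h and 24 h with Epo. The untreated arrays end at 7 h, so the Epo arrays of 8 to 24 h entered the late comparison only.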

Results

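Expression was measured on 20 arrays of mouse erythroid progenitors at the colony-forming unit erythroid (CFU-E) stage, the stage at which red cell precursors depend on the hormone erythropoietin (Epo). The cells were isolated from fetal livers of BALB/c mice by magnetic removal of other cell types. In the series with Epo (0.5 U/ml), 12 arrays covered 0 to 8 h hourly and 14, 19 and 24 h, and in the series without Epo 8 arrays covered 0 to 7 h hourly. Each treatment and time had 1 array, and the number of arrays limits the precision. Nothing in the labels states that the times came from separate cultures, so the p-values measure the scatter between arrays at successive times, which may be technical. The study concerned feedback by inhibitors that Epo induces in the pathway from the Epo receptor through the kinase JAK2 to the transcription factor STAT5. The labels describe the cells before stimulation in different ways, as starved shortly after sorting and as cultured with Epo beforehand.

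At 0 h, before the stimulation that the labels describe, the series already differed: 551 of 18194 genes lay apart by at least 1 on the log2 scale, 436 of them higher in the series with Epo. Hepatocyte markers were higher there in 13 of 13 genes (median log2 difference 1.40), and granulocyte markers in 0 of 13 (median -0.62). The chaperone gene Hspa1a differed by 3.06 at 0 h and the transcription factor gene Jun by 2.03. Of the array controls, some separated the series at 0 to 7 h and others did not, all tested after their values were seen. The spiked-in lys control lay at 7.58 ± 0.31 (SD, n = 8) with Epo and 6.73 ± 0.18 (n = 8) without (2-sided exact permutation test, p = 0.00016, the smallest it can give). An 18S ribosomal RNA probe set lay at 6.30 ± 0.42 and 8.48 ± 0.67 (same exact permutation test, p = 0.00016, n = 8 each). The bioB control differed by 0.47 (exact permutation p = 0.0023, n = 8 each) and thr by -0.57 (exact permutation p = 0.039, n = 8 each). The phe control differed by 0.24 (exact permutation p = 0.065, n = 8 each) and dap by 0.10 (exact permutation p = 0.45, n = 8 each). Because of the differences at 0 h, the change from each series' own 0 h array is given too, a choice made after seeing the data. It is given where it turned, ended or made a list's call and for lists called between the series. For named genes it is given where it moved the difference by over 1.5 times or turned it. It rests on a single pair of 0 h arrays and is less precise than the differences themselves. A call lost there thus does not show that a difference was absent.

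The first comparison asked which genes Epo changed within 7 h, as the mean of the 7 matched differences at 1 to 7 h (log2, Epo minus no Epo, ± SE, n = 7 pairs). Higher and lower refer here to the difference between the series, not to a change in level with Epo. Some inhibitors of the receptor pathway were higher with Epo. Socs3, which blocks JAK2 activity at the receptor, was higher by 3.05 ± 0.14 (adjusted p = 7.9e-07), Cish, which competes with STAT5 for the receptor, by 2.26 ± 0.12 (adjusted p = 8.0e-07) and Socs2 of the same family by 1.61 ± 0.32 (adjusted p = 0.0018). From their own 0 h arrays these differences were 2.58, 2.15 and 1.69. Each passed the test with drift allowed, but only Socs3 passed without drift. Cish reached 9.14 at 1 h from 6.37 at 0 h with Epo and then lay between 7.88 and 8.66, against 5.46 to 6.81 at 1 to 7 h without Epo. Socs3 went from 4.36 to 7.26 within 1 h, against 3.50 to 4.18 without Epo. Pim1, a survival kinase gene and STAT5 target, was higher by 1.94 ± 0.16 (2.34 from its own 0 h; adjusted p = 5.1e-06).

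**Figure D1:**
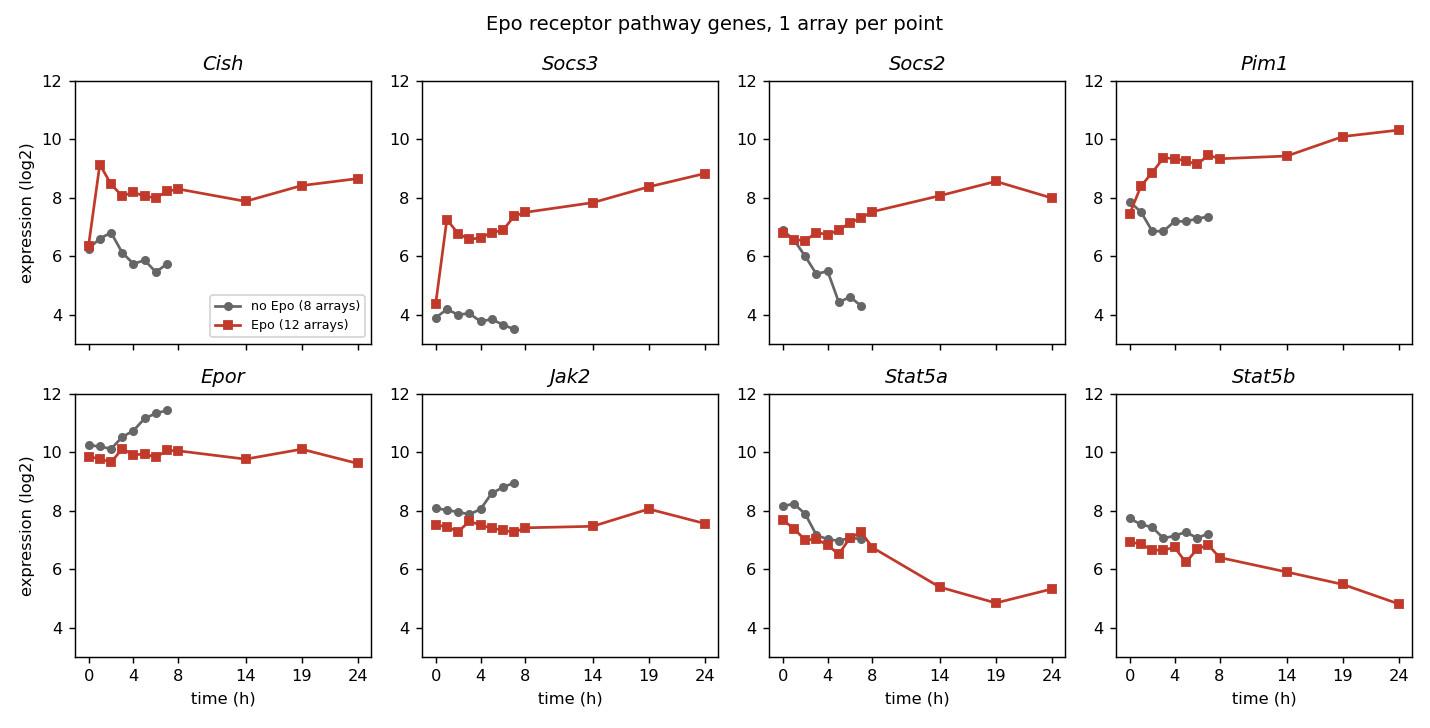
Expression (log2) against time (h) of genes of the Epo receptor pathway, 1 array per point, without Epo (grey circles, 8 arrays) and with Epo (red squares, 12 arrays). With Epo, Cish stood at 9.14 and Socs3 at 7.26 at 1 h, against 6.60 and 4.18 without.

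The genes of the receptor Epor, the kinase Jak2 and Stat5b were lower between the series. The difference for Epor, the receptor itself, was -0.89 ± 0.14 (adjusted p = 0.00053). For Jak2 it was -0.91 ± 0.17 (adjusted p = 0.0012) and for Stat5b -0.58 ± 0.11 (adjusted p = 0.0012). Stat5a was at -0.33 ± 0.14 (adjusted p = 0.089), and passes without 7 h (-0.42, adjusted p = 0.040), after median centring (adjusted p = 0.048) or as the mean of its probe sets (-0.71, adjusted p = 0.0050). With Epo, Epor went from 9.85 at 0 h to 10.07 at 7 h, and without Epo from 10.25 to 11.44. From their own 0 h the differences of these 4 genes were -0.49, -0.34, 0.23 and 0.15, in the order named, and none passed. Of 21 receptor pathway components 1 was higher and 10 lower, as many adjusted over the list alone (median -0.30, camera adjusted p = 0.0016), with Pik3r1, a regulatory subunit of PI3 kinase, at -1.64 ± 0.16 (-0.84 from its own 0 h). For this list the adjusted p = 0.224 with an estimated correlation, and from the own 0 h with drift allowed its median was 0.04 (camera adjusted p = 0.54). Of 20 negative regulators of JAK2 and STAT5, 4 were higher and 11 lower (4 and 12 adjusted over the list alone); the median was -0.31 and the mean 0.07 (camera adjusted p = 0.26), and the ubiquitin ligase gene Cblb was lower, at -1.07 ± 0.16 (-0.55 from its own 0 h). The list lay at -0.32 at 0 h, and from the own 0 h, with drift allowed, its direction turned: the median was 0.14, with 4 higher and 0 lower (camera adjusted p = 0.0051; adjusted p = 0.215 with an estimated correlation). Of 21 STAT5 targets 6 were higher and 7 lower, the same counts adjusted over the list alone (median 0.06, camera adjusted p = 0.77). From the own 0 h with drift allowed, 5 STAT5 targets were higher and 1 lower (median 0.19, camera adjusted p = 0.019; adjusted p = 0.215 with an estimated correlation).

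FOXO targets, brakes of the cell cycle and ATF4 response genes were lower with Epo as lists with the preset correlation. Txnip, an inhibitor of glucose uptake and thioredoxin, was lower, at -4.36 ± 0.16 (adjusted p = 2.6e-07; -4.45 from its own 0 h). Klf10, a repressor gene induced by TGF-beta (-3.34 ± 0.33), was lower too, as were the FOXO target Tsc22d3 (-3.26 ± 0.28) and Ddit3, which encodes the stress factor CHOP (-2.90 ± 0.21). Of 24 FOXO targets 1 was higher and 11 lower (1 and 12 adjusted over the list alone; median -0.34, adjusted p = 0.439 with an estimated correlation against 0.0014 with the preset). Of 14 CDK inhibitors and brakes of the cell cycle 1 was higher and 10 lower (2 and 10 over the list alone; median -0.91), among them Ccng2 (-2.31 ± 0.41), the antiproliferative genes Btg2 (-2.22 ± 0.18) and Btg1 (-2.14 ± 0.30), and Cdkn1b (-2.04 ± 0.30), which encodes p27. That list's camera adjusted p was 0.0012, and adjusted p = 0.467 with an estimated correlation. Of 30 ATF4 and amino acid response genes 2 were higher and 19 lower, as many over the list alone (median -0.63, camera adjusted p = 0.00017; adjusted p = 0.475 with an estimated correlation). With drift allowed, the median from the own 0 h was -0.34 for ATF4 response genes (0 higher, 3 lower), -0.63 for the brakes (0 and 6) and -0.40 for FOXO targets (0 and 4). Of 30 immediate early and ERK feedback genes 7 were higher and 15 lower (8 and 15 over the list alone; median -0.32, camera adjusted p = 0.020). For these, adjusted p = 0.224 with an estimated correlation and 0.065 after median centring, and members moved apart: Jun was lower, at -3.14 ± 0.18 (-5.17 from its own 0 h), as was Ier2 at -2.73 ± 0.17, while Egr1, a transcription factor gene downstream of ERK, was higher by 2.33 ± 0.23. The median of this list from the own 0 h with drift allowed was -0.61, with 1 higher and 9 lower. Of 17 pro-apoptotic genes 4 were higher and 8 lower (median -0.32, camera adjusted p = 0.16), with Bbc3, which encodes PUMA, at -2.33 ± 0.24 and Bnip3 at 1.29 ± 0.10 (0.46 from its own 0 h); of 13 anti-apoptotic genes 3 were higher and 5 lower (median -0.17, camera adjusted p = 0.77). Adjusted over those lists alone the counts were 4 and 9, and 4 and 6.

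Sterol synthesis genes were higher together. Of 20 cholesterol synthesis genes 17 were higher and 1 lower, as many adjusted over the list alone (median 0.93, camera adjusted p = 9.7e-06; adjusted p = 0.509 with an estimated correlation). Msmo1, a sterol demethylating oxidase gene, was higher by 2.66 ± 0.33, Idi1 by 1.81 ± 0.28, Hmgcs1 by 1.59 ± 0.27 and Fdft1, squalene synthase, by 1.52 ± 0.22. The list already lay 0.49 higher at 0 h, and from the own 0 h its median was 0.45, with 3 of 20 called higher and 0 lower with drift allowed. Msmo1 lay at 1.54 from its own 0 h, Idi1 at 0.99, Hmgcs1 at 0.68 and Fdft1 at 0.87. Hepatocyte markers were higher too between the series, at a median of 1.00 after 1.40 at 0 h, but at -0.33 from their own 0 h. Other genes among the 10 highest were Fhl1, a LIM domain protein gene (3.42 ± 0.43), Srxn1, which reduces oxidised peroxiredoxins (3.09 ± 0.27), Ccnb1ip1 (3.00 ± 0.39) and Mtf1, a metal-responsive transcription factor gene (2.69 ± 0.22, or 1.64 from its own 0 h). A probe set annotated to the microRNA gene Mir1949 (3.29 ± 0.28), 1 of the ribosomal protein gene Rpl12 (3.05 ± 0.21), and those of the histone genes H3c4 (2.69 ± 0.15) and H3c7 (2.69 ± 0.17), which have near-identical copies, completed them. From their own 0 h, H3c4 was at 1.32 and H3c7 at 0.82. The Rpl12 probe set was dim for such a gene: at 0 h without Epo it lay at 5.57, against a median of 13.68 over 43 ribosomal protein genes. Among the 10 lowest were also Net1 (-3.11 ± 0.23, or -1.85 from its own 0 h), Cyp1a1, a target of the aryl hydrocarbon receptor (-2.93 ± 0.40), and Zkscan14 (-2.88 ± 0.25). Of 28 ribosome biogenesis genes 8 were higher and 3 lower, the same over the list alone (median 0.20, camera adjusted p = 0.44), with Rrp9 at 0.88 ± 0.24. They lay at -0.31 at 0 h, and from the own 0 h with drift allowed 6 were higher and 0 lower (median 0.51, camera adjusted p = 1.3e-08; adjusted p = 0.215 with an estimated correlation).

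Erythroid transcription factors, red cell membrane genes and cell cycle genes were lower with Epo between the series, and less so from their own 0 h. Of 19 erythroid transcription factors 1 was higher and 15 lower, as many over the list alone (median -0.60, camera adjusted p = 1.4e-06; adjusted p = 0.224 with an estimated correlation), with Klf3 at -2.02 ± 0.21 and Gfi1b at -1.58 ± 0.13. Of 26 red cell membrane and terminal differentiation genes 3 were higher and 16 lower (4 and 17 over the list alone; median -0.46, camera adjusted p = 0.00060; adjusted p = 0.482 with an estimated correlation). The water channel gene Aqp1 was at -1.53 ± 0.26 and Dmtn, a membrane skeleton gene, at -1.27 ± 0.15. Of 13 heme synthesis genes 3 were higher and 7 lower, the same over the list alone (median -0.21, camera adjusted p = 0.24), with the mitochondrial transporter gene Abcb10 at -1.49 ± 0.22. Of 6 globin genes 2 were higher and 2 lower (2 and 2 over the list alone; median -0.07, mean 0.08, camera adjusted p = 0.95). Of 18 progenitor genes 1 was higher and 9 lower (2 and 11 over the list alone; median -0.28, camera adjusted p = 0.0012; adjusted p = 0.224 with an estimated correlation), and Kit, the stem cell factor receptor gene, was at -2.17 ± 0.21 with -1.40 already at 0 h and -0.77 from its own 0 h. The progenitor list lay at -0.26 at 0 h, and its call ended from the own 0 h with drift allowed (median -0.13, 1 higher and 0 lower, camera adjusted p = 0.93). Of 14 iron uptake and storage genes 3 were higher and 8 lower, the same over the list alone (median -0.35, camera adjusted p = 0.082, and 0.049 without 3 h). Of 27 G1/S genes 3 were higher and 18 lower (3 and 19 over the list alone; median -0.67), with Cdc6, a replication licensing gene, at -1.62 ± 0.18. Of 27 G2/M genes 1 was higher and 20 lower, as many over the list alone (median -0.65), with the spindle genes Kif11 at -1.81 ± 0.20 and Nusap1 at -1.62 ± 0.31. Their camera adjusted p were 4.4e-05 and 9.7e-06, and the adjusted p = 0.482 and 0.509 with an estimated correlation. At 0 h the medians already lay at -0.31 for erythroid transcription factors, -0.32 for G1/S, -0.26 for G2/M and -0.08 for red cell membrane genes. With drift allowed, those from the own 0 h were -0.36 (0 higher, 1 lower), -0.35 (1 and 1), -0.29 (0 and 2) and -0.29 (0 and 5).

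The remaining lists passed no camera test in this comparison, apart from hepatocyte markers. Of 21 glycolysis and hypoxia genes 3 were higher and 9 lower (4 and 9 over the list alone; adjusted p = 0.11), and of 18 heat shock and unfolded protein genes 2 and 6 (3 and 6; 0.32). Of 21 p53 targets 7 were higher and 7 lower (7 and 8; 0.77), of 22 interferon response genes 2 and 6 (2 and 6; 0.24) and of 17 autophagy and mitophagy genes 5 and 7 (6 and 7; 0.98). The chaperone gene Hspa1a was lower, at -1.95 ± 0.31 after being 3.06 higher at 0 h, which makes -5.01 from its own 0 h. The interferon-induced genes Gbp3 (-2.54 ± 0.40) and Usp18 (-1.71 ± 0.26) were lower. Among markers of other cells, 11 of 13 hepatocyte genes were higher between the series, as many over the list alone (median 1.00, camera adjusted p = 2.6e-07; adjusted p = 0.318 with an estimated correlation). The plasma protein genes Apoa2 and Ttr were at 1.88 ± 0.10 and 1.87 ± 0.09, and from their own 0 h at 0.07 and 0.13. From the own 0 h with drift allowed, the hepatocyte median was -0.33, with 0 of 13 called (camera adjusted p = 0.019, lower; adjusted p = 0.506 with an estimated correlation). Of 13 granulocyte markers 1 was higher and 2 lower (the same over the list alone; adjusted p = 0.74), with Mpo, a neutrophil granule enzyme gene, at -1.48 ± 0.24 after -2.26 at 0 h and 0.78 from its own 0 h. Macrophage (2 of 18 higher, 0 lower; adjusted p = 0.95), megakaryocyte (2 higher and 2 lower of 12; 0.98) and mast cell and basophil markers (1 of 9 higher; 0.97) gave the same counts over the list alone. Of 13 lymphoid markers 1 was higher (0 over the list alone; 0.54), and of 13 endothelial and stromal markers 3 were higher and 1 lower (6 and 1; 0.31). Other lists with no call between the series had one from the own 0 h with drift allowed: globins (median -0.45, camera adjusted p = 0.016), heme synthesis (-0.27, 0.0067), p53 targets (-0.37, 0.022) and interferon response genes (-0.20, 0.037) lower, and granulocyte (0.78, 7.8e-06) and mast cell and basophil markers (0.42, 0.0029) higher. None of these calls held with an estimated correlation (adjusted p = 0.215, 0.395, 0.350, 0.231, 0.215 and 0.215).

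Over all genes 3304 were higher and 3669 lower with Epo than without (limma, adjusted p under 0.05, 38.3% of 18194), 520 and 667 of them at least 2-fold, and 4988 of the 6973 had the same sign in all 7 pairs. With each array centred on its median the split was 2383 and 4479, so the share of higher genes moved from 47.4% to 34.7%. Among the brighter genes alone it was 2289 and 3290. At 1 to 7 h the values of the arrays with Epo spanned a narrower range (SD 2.48 to 2.51) than those without (2.53 to 2.56). From the own 0 h arrays 4 genes were higher and 13 lower (1447 at an unadjusted p under 0.05), and 252 and 454 with drift allowed. Subtracting a single 0 h pair lowers the precision, so these counts do not measure how many differences were present at 0 h. Without drift, a change of the difference over the hours also counts as scatter. Of the 6973 genes, 5478 kept their direction from the own 0 h, 525 passed again with drift allowed and 53 passed in the opposite direction. Already at 0 h, 5646 of the 6973 differed in the called direction. Of the 1187 called at least 2-fold, 410 were also at least 2-fold apart in that direction from their own 0 h. Without the 2 h pair, where an array stood apart in its control transcripts, 3051 were higher and 3559 lower.

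More genes differed between the series at 2 to 7 h than at 0 or 1 h, with 1 array on each side and no test. A log2 difference of at least 1 was found in 551 genes at 0 h, 460 at 1 h, 1301 at 2 h, 1188 at 3 h, 1447 at 4 h, 2403 at 5 h, 2118 at 6 h and 1939 at 7 h. At 7 h, 2019 genes lay at least 2-fold from their own 0 h level without Epo and 763 with Epo. Socs2 was 0.01 higher with Epo at 1 h and 3.02 higher at 7 h, whereas Cish was 2.54 and 2.48 higher at these times.

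**Figure D2:**
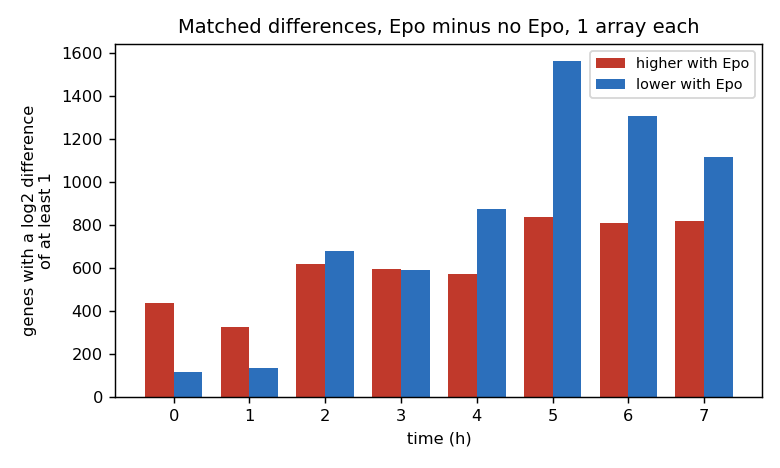
Number of genes whose log2 difference, Epo minus no Epo, was at least 1 in size at each hour (h), higher (red) or lower (blue) with Epo, from 1 array per treatment and hour. The 0 h bars, 436 higher and 115 lower, show the difference before stimulation, and at 5 h the counts were 837 and 1566.

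The change of the Epo effect from 1 to 7 h was measured as the slope of the matched differences (log2 per h, ± SE, n = 7 pairs). Climbed and fell refer here to the difference between the series. The effect climbed fastest for Csf2rb, the shared receptor chain for interleukin 3 and related cytokines (0.77 ± 0.05, adjusted p = 4.0e-06), the sialomucin gene Podxl (0.63 ± 0.06), Gdf3 (0.59 ± 0.05), Ccnb1ip1 (0.58 ± 0.08), Ogt, which encodes the O-GlcNAc transferase (0.57 ± 0.06), and the fatty acid synthase gene Fasn (0.55 ± 0.06). It fell fastest for Relb, an NF-kB subunit gene (-1.09 ± 0.10, adjusted p = 1.3e-05), Klhl24 (-0.83 ± 0.11), Btn1a1 (-0.69 ± 0.09), Rrad (-0.66 ± 0.10), Ndrg1 (-0.66 ± 0.10) and Ccng2 (-0.59 ± 0.10). The Socs2 difference grew by 0.50 ± 0.05 per h (adjusted p = 2.3e-05). Slopes of Cish (0.07 ± 0.05, adjusted p = 0.52), Pim1 (0.10 ± 0.06, 0.36), Stat5b (0.04 ± 0.05, 0.74) and Socs3 (0.13 ± 0.06, 0.13) did not pass; Socs3 passes without 1 h (0.22, adjusted p = 0.023). Those of Epor (-0.21 ± 0.03) and Jak2 (-0.21 ± 0.05) were negative and that of Stat5a (0.17 ± 0.05) positive, Jak2 losing its call without 7 h (adjusted p = 0.082) and Stat5a without 1, 2, 6 or 7 h (0.075 to 0.12).

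The differences of most ribosome biogenesis and sterol synthesis genes climbed over these hours. Of 28 ribosome biogenesis genes 25 climbed and 0 fell (26 adjusted over the list alone; median slope 0.23, camera adjusted p = 1.8e-19; adjusted p = 0.153 with an estimated correlation), with Rrp9 and Bop1 at 0.38 ± 0.04 each. Of 20 cholesterol synthesis genes 15 climbed (17 over the list alone; median 0.33, camera adjusted p = 1.3e-17; adjusted p = 0.151 with an estimated correlation), with Msmo1 at 0.51 ± 0.05 and Idi1 at 0.45 ± 0.04. Of 18 heat shock and unfolded protein genes 9 climbed (11 over the list alone; median 0.12, adjusted p = 0.219 with an estimated correlation), with the endoplasmic chaperone gene Hsp90b1 at 0.44 ± 0.04. Of 27 G2/M genes 9 fell (12 over the list alone; median -0.10, adjusted p = 0.517 with an estimated correlation), with Nusap1 at -0.50 ± 0.04. Of 14 CDK inhibitors and brakes 6 fell, as many over the list alone (median -0.13, adjusted p = 0.153 with an estimated correlation), with Cdkn2c at -0.47 ± 0.06. Of 27 G1/S genes 1 climbed and 10 fell (1 and 14 over the list alone). The globin slopes fell in 3 of 6 genes, as many over the list alone (median -0.12, adjusted p = 0.153 with an estimated correlation). The 1 h pair decided the list calls for heme synthesis, red cell membrane, G1/S, FOXO and granulocyte genes: without it their camera adjusted p were 0.35, 0.40, 0.070, 0.19 and 0.72, from 0.022, 0.021, 0.0039, 0.015 and 0.025. With an estimated correlation these 5 had an adjusted p = 0.52, 0.61, 0.58, 0.40 and 0.57. The ATF4 list, in contrast, gained a call to climbing without the 1 h pair (camera adjusted p = 2.2e-05, from 0.38 with it). Over all genes the slope was positive in 1325 and negative in 1454 (15.3%). Without the 6 h pair the counts were 866 and 863, without 2 h they were 999 and 1075, and as the difference between the means of 4 to 7 h and 1 to 3 h they were 610 and 929.

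Time without Epo was examined as the slope over 0 to 7 h (log2 per h, ± SE, n = 8 arrays). Red cell genes rose in cells kept without the hormone, while hepatocyte markers fell in 13 of 13 cases (median -0.29 per h) and granulocyte markers in 7 of 13. Signs of RNA quality moved over these hours too: without Epo the Gapdh 3' minus 5' difference went from -0.089 at 0 h to -0.166 at 2 h and 0.085 at 7 h, and that of Actb from 0.578 to 0.394 and 0.621. With Epo, Gapdh lay between -0.171 and -0.083 at 1 to 7 h. Of 13 heme synthesis genes 11 rose and 1 fell, as many adjusted over the list alone (median 0.16 per h, camera adjusted p = 9.3e-07; adjusted p = 0.043 with an estimated correlation). Alas2, the rate-limiting erythroid enzyme of heme synthesis, rose by 0.48 ± 0.04 per h (adjusted p = 1.1e-05) and Abcb10 by 0.31 ± 0.03. Of 26 red cell membrane and terminal differentiation genes 19 rose and 1 fell (20 and 1 over the list alone; median 0.14, adjusted p = 0.106 with an estimated correlation), with Tent5c, a poly(A) polymerase gene, at 0.40 ± 0.04 and Dmtn at 0.36 ± 0.03. Of 19 erythroid transcription factors 12 rose and 2 fell (13 and 2 over the list alone; median 0.13, adjusted p = 0.116 with an estimated correlation), among them Foxo3 (0.35 ± 0.05) and Nfe2 (0.34 ± 0.04). Of 6 globin genes 4 rose (5 over the list alone; median 0.11, adjusted p = 0.116 with an estimated correlation), the embryonic Hbb-bh1 by 0.33 ± 0.02.

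Ribosome biogenesis genes fell in 26 of 28 cases without Epo and rose in 0, the same over the list alone (median -0.18 per h, adjusted p = 0.116 with an estimated correlation), with Bop1 at -0.33 ± 0.03 and Ddx21, a nucleolar helicase gene, at -0.28 ± 0.02. Glycolysis and hypoxia genes fell in 14 of 21 cases and rose in 2, the same over the list alone (adjusted p = 0.106 with an estimated correlation), with the hexokinase gene Hk2 at -0.32 ± 0.04. Heat shock and unfolded protein genes fell in 12 of 18 and rose in 1 (13 and 1 over the list alone; adjusted p = 0.168 with an estimated correlation), with Hsp90b1 at -0.44 ± 0.04. Among 14 CDK inhibitors and brakes 7 rose and 1 fell, the same over the list alone (median 0.23, adjusted p = 0.106 with an estimated correlation), with Ccng2 at 0.54 ± 0.09. Cell cycle genes rose as well without Epo: of 27 G1/S genes 17 rose and 4 fell, the same over the list alone (camera adjusted p = 0.00078; adjusted p = 0.284 with an estimated correlation). Of 27 G2/M genes 12 rose and 0 fell (13 and 1 over the list alone; camera adjusted p = 8.6e-06; adjusted p = 0.331 with an estimated correlation). The cytokine-responsive genes Socs2 (-0.39 ± 0.03) and Ccnd2, a cyclin gene (-0.34 ± 0.03), fell. The largest slopes included Cyp1a1 (1.12 ± 0.24), the p53 target Trp53inp1 (0.71 ± 0.05), Ddit3 (0.64 ± 0.13), Trib3, a stress-induced pseudokinase gene (0.62 ± 0.14), and the acetylcholinesterase gene Ache (0.57 ± 0.05). Those that fell included Ccnb1ip1 (-0.56 ± 0.04), Rgn (-0.54 ± 0.03), Podxl (-0.51 ± 0.03) and Ada, the adenosine deaminase gene (-0.51 ± 0.05).

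Within the receptor pathway, Epor rose by 0.21 ± 0.02 per h without Epo and Stat5a fell by 0.20 ± 0.04 per h. Jak2 rose by 0.14 ± 0.03 (adjusted p = 0.0066, and 0.056 without 7 h) and Cish fell by 0.15 ± 0.04 (adjusted p = 0.012, and 0.053 without 6 h). Socs3 fell by 0.07 ± 0.02 (adjusted p = 0.046), a call lost without any of 1 to 7 h (0.051 to 0.23) and on another probe set. Stat5b (-0.08 ± 0.03, adjusted p = 0.057) passes without 3 or 7 h (0.026 and 0.041) and after quantile normalization (0.034), and Pim1 was at -0.04 ± 0.04 (adjusted p = 0.57). Hepatocyte markers fell in 13 of 13 cases, all over the list alone (median -0.29, adjusted p = 0.116 with an estimated correlation), with Ttr at -0.38 ± 0.03 per h. Granulocyte markers fell in 7 of 13 cases, as many over the list alone (median -0.07, camera adjusted p = 0.0019, 0.093 without 0 h; adjusted p = 0.338 with an estimated correlation), with Mpo at -0.50 ± 0.03. Over all genes 2432 rose and 2799 fell (limma, 28.8%).

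**Figure D3:**
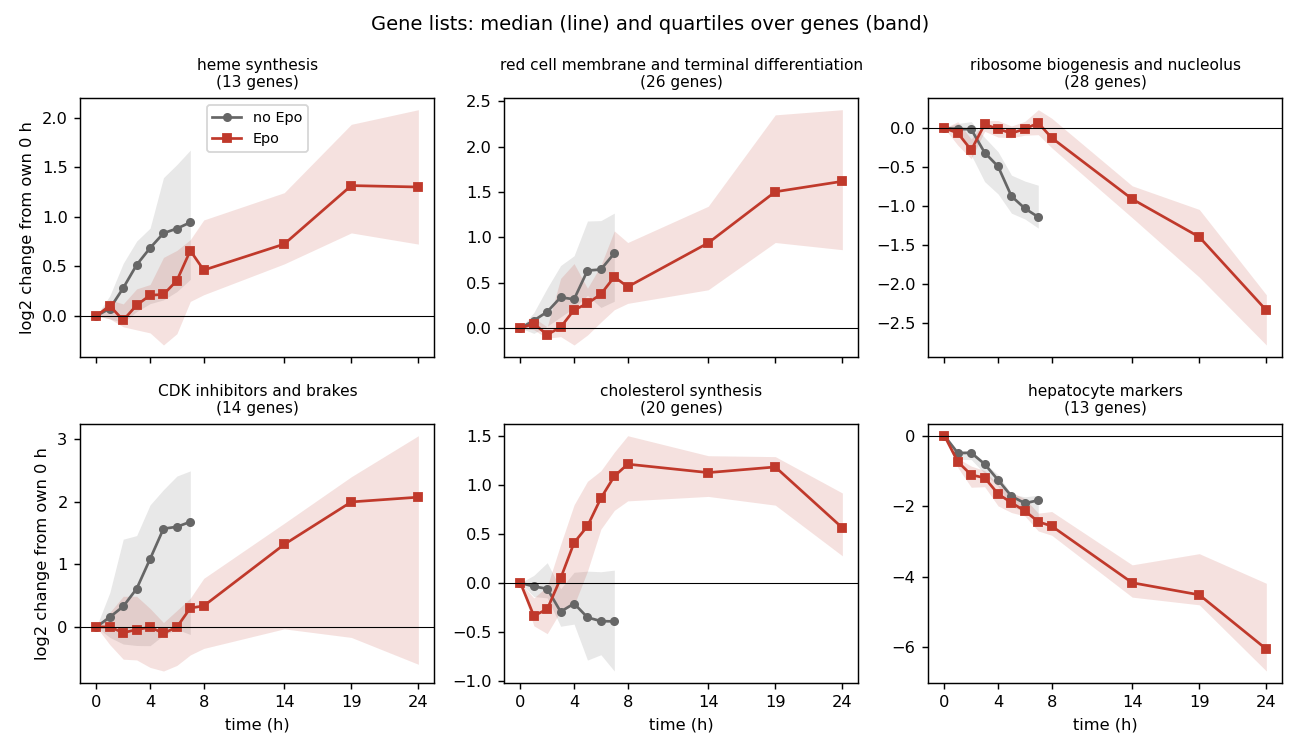
Median log2 change from the own 0 h array over the genes of 6 lists against time (h), with bands from the lower to the upper quartile over genes, without Epo (grey) and with Epo (red). Ribosome biogenesis stood at -1.14 at 7 h without Epo and 0.07 with it, and hepatocyte markers at -1.83 and -2.44.

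Later changes under Epo were taken as the mean of 14, 19 and 24 h minus that of 1 to 8 h (log2, ± SE, n = 3 and 8 arrays). No untreated arrays of these times were used here, so culture time and Epo cannot be told apart. The 10 largest rises included these genes: Alas2 rose by 3.20 ± 0.44 (adjusted p = 1.0e-04), Ypel5 by 3.48 ± 0.30, Fn3k, which repairs glycated proteins, by 3.88 ± 0.50, Ncf4, an oxidase subunit gene, by 3.70 ± 0.55, Rragd, a GTPase gene of lysosomal mTOR signalling, by 3.27 ± 0.31 and Ccng2 by 3.85 ± 0.42. Of 26 red cell membrane and terminal differentiation genes 23 rose and 1 fell, the same adjusted over the list alone (median 0.96, camera adjusted p = 2.6e-09; adjusted p = 0.231 with an estimated correlation). Ypel4 was at 3.06 ± 0.33, the nuclear exporter gene Xpo7 at 2.45 ± 0.40 and Aqp1 at -2.71 ± 0.59. Of 13 heme synthesis genes 11 rose, as many over the list alone (median 1.15; adjusted p = 0.231 with an estimated correlation), among them Uros at 1.45 ± 0.22. Of 6 globin genes 4 rose (5, with 1 fall, over the list alone; median 0.71, adjusted p = 0.231 with an estimated correlation), Hbb-bh1 by 2.19 ± 0.24.

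Ribosome biogenesis genes fell late in 28 of 28 cases, all over the list alone (median -1.54, camera adjusted p = 2.2e-18; adjusted p = 0.231 with an estimated correlation), with the assembly factor gene Rrp12 at -2.15 ± 0.33 and Nolc1 at -2.08 ± 0.27. Myc, a growth regulator, fell by 1.72 ± 0.25 and Myb, a progenitor transcription factor gene, by 2.58 ± 0.32. CDK inhibitors and brakes rose in 8 of 14 cases and fell in 1 (9 and 1 over the list alone; median 1.39, adjusted p = 0.231 with an estimated correlation), Cdkn1b by 2.77 ± 0.30 and Cdkn2d by 2.70 ± 0.27. Of the G2/M genes 21 of 27 also rose (22 over the list alone; median 0.51, adjusted p = 0.231 with an estimated correlation), the mitotic phosphatase gene Cdc25b by 2.57 ± 0.27. Of 30 ATF4 and amino acid response genes 16 rose and 4 fell (17 and 4 over the list alone; median 0.55, adjusted p = 0.390 with an estimated correlation), Ddit3 by 3.20 ± 0.38 and Trib3 by 2.94 ± 0.45. Of 17 autophagy and mitophagy genes 12 rose and 2 fell, the same over the list alone (median 0.75, adjusted p = 0.251 with an estimated correlation), with the autophagosome marker gene Map1lc3b at 1.31 ± 0.13. Egr1 fell by 3.91 ± 0.72.

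In the receptor pathway, Socs3 rose further by 1.37 ± 0.23 (adjusted p = 0.00037) and Socs2 by 1.27 ± 0.21, while Stat5a fell by 1.80 ± 0.18 and Stat5b by 1.24 ± 0.20. Pim1 rose by 0.80 ± 0.22 (adjusted p = 0.011), a call lost without 19 h (0.054) or 24 h (0.081). Cish (0.01 ± 0.22, adjusted p = 0.96), Epor (-0.09 ± 0.13, 0.60) and Jak2 (0.28 ± 0.14, 0.13, but 0.0090 after quantile normalization) did not pass. Hepatocyte genes fell late. Of 13 markers 11 fell, as many over the list alone (median -3.07, camera adjusted p = 3.5e-08; adjusted p = 0.231 with an estimated correlation), with Ttr at -4.69 ± 0.62. Fabp1, a fatty acid binding protein gene of liver, was at -4.52 ± 0.50 and Apoc2, an apolipoprotein gene, at -4.41 ± 0.47. Over all genes 3217 rose and 3360 fell (limma, 36.1%), 454 and 1197 at least 2-fold. Centring each array on its median gave 2215 and 3736, so that the share of higher genes moved from 48.9% to 37.2%. Quantile normalization moved it the other way, to 55.9%, with 3529 higher and 2789 lower. Without 24 h, where the array's values spanned a narrower range, 1830 rose and 2417 fell, and among the brighter genes alone 1776 rose and 3279 fell.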

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

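The tests of array processing, sort purity, hepatocyte RNA, a constant offset, Epo withdrawal and leftover Epo signalling were chosen only after the result was seen; those of scaling, ribosomal protein transcripts and other splits were fixed beforehand.

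Of 62 sets of values searched for a value far from the others, 6 held one, where chance gives about 1 in 20. Arrays with Epo were compared over 1 to 7 h, and matched differences likewise. The 2 h array with Epo stood apart in the Actb 3' minus 5' difference (0.999, the others 0.585 to 0.664) and in the spiked-in thr control (10.0, the others 7.92 to 8.37). The 6 h array with Epo stood apart in an 18S ribosomal RNA probe set (7.28, the others 6.01 to 6.27). The Pim1 difference between the series at 1 h was 0.89, against 1.86 to 2.51 at 2 to 7 h. The median difference of immediate early and ERK feedback genes was -0.018 at 5 h, against -0.50 to -0.29 at the other hours of 1 to 7 h, and that of macrophage markers 0.19 at 3 h, against -0.05 to 0.02. With the slope without Epo and the difference itself tested, 1239 genes had slopes of opposite sign in the series, 694 of them rising and 545 falling without Epo. The slope with Epo was not tested, so genes nearly flat with Epo are counted too. The 2 tests also share the arrays without Epo.

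The series differed at 0 h, and separate processing of their arrays is a candidate cause: the lys control, which carries nothing of the cells, differed by 0.85 at 0 to 7 h (exact permutation p = 0.00016, n = 8 each), though dap differed by only 0.10 (exact permutation p = 0.45). A lower purity of one sort for all other cell types alike is argued against by granulocyte markers at -0.62 and hepatocyte markers at 1.40. A purity that differed by cell type between the sorts stays open, since it allows opposite signs. More hepatocyte RNA with Epo stays open, since 13 of 13 markers higher (Alb at 13.16 against 12.09, Afp at 13.03 against 12.72) is the pattern itself and tests nothing. A constant offset as the whole cause of the genes called at 1 to 7 h is argued against, because of 3454 genes called from 1, 3, 5 and 7 h, 81.3% moved beyond their 0 h difference in the called direction at 2, 4 and 6 h, with a median over all of them of 0.38. The share was 72.9% for higher and 88.0% for lower genes. Before subtraction of 0 h, their median difference at 1, 3, 5 and 7 h was 0.80 in the called direction. All rest on the same pair of 0 h arrays, and a series difference that drifts with time was not tested. How much of a single gene's difference is Epo stays open, since culture and arrays of the series cannot be told apart from it.

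Hepatocyte transcripts had negative slopes over time in both series. A scaling shift of bright transcripts would move equally bright genes alike, yet the markers' median slope without Epo was -0.29 per h and the lowest of 10000 random lists of equally bright genes was at -0.16. Withdrawal of Epo is argued against by a median slope of -0.31 with Epo, where 13 of 13 slopes were negative. Between the series 0 slopes differed at an adjusted p under 0.05 in limma. That count adds little, since on simulated data the fit of the change at 1 to 7 h called 14.9% of changes of 1 over the span. Loss of hepatocytes or their RNA in culture may account for it and was not tested; the antibodies of the sort, per the labels, were against blood cell markers. No biological explanation other than Epo was tested.

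Red cell genes rose without Epo. Stable transcripts kept while other RNA decays cannot be told apart from other explanations: the 43 ribosomal protein transcripts, which should then rise, had a median slope of -0.0056 per h, but 34 lay near the top of the scale and 4 were dim. The 5 others all had negative slopes, too few to decide. Epo signalling left over from earlier culture cannot be told apart either, since Cish at least 1.66 below freshly stimulated cells at each of 1 to 7 h sets no bound on it. With the heme synthesis median at 0.078 per h with Epo and 0.16 without, maturation in culture regardless of Epo stays open as a biological explanation, and so do a loss of other cells' RNA, with hepatocyte markers at -0.29 per h without Epo, and RNA quality, with the Gapdh 3' minus 5' difference at -0.089 at 0 h and 0.085 at 7 h; none of these was tested.

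Other splits of the arrays were counted for each comparison. For the Epo effect, 1 of 64 exchanges of the series within times called as many genes as the real 6973, the real one itself; the highest other called 3397 and exchanged the 1 h pair alone. For the change of the Epo effect the real order of times called 2779 and the highest other of 100 orders 500, for time without Epo 5231 and 2248, and for the late comparison 6577 and 0 of 100 splits drawn from 165, with 1 as large in each. A random order or split of the arrays is thus argued against for the 4 counts. Successive arrays may come from 1 culture, so a smooth drift over time would also favour the real order. Such a drift cannot be excluded in this way, and the series difference at 0 h is not addressed.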

How the results depend on the processing

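The subtraction of each gene's 0 h difference, the added 0 h difference in the slope and the readouts without 2 h or 24 h with Epo were tests chosen only after the result was seen; the others were fixed beforehand.

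Of 2730 values of named genes under the processing choices fixed beforehand, 2692 stayed on their side of the threshold, called ones with their direction, 26 lost their call, 11 gained one and 1 turned: Socs3 without Epo, 0.0035 per h on the brightest probe set without the suffixes _x_at or _s_at. Of 2034 values of lists, 1906 stayed likewise, uncalled lists included, 89 lost their call, 39 gained one and 0 turned. Most of the lost calls came from the estimated correlation. It ended 12 list calls for the Epo effect, 12 for its change, 17 for time without Epo and 12 for the late comparison. Only the heme synthesis call without Epo remained there. The named genes were largely picked for the size of their change in these data, which favours such stability. For the Epo effect, the brighter genes alone kept 74.8% of all calls in the same direction, with only 9097 genes tested. With all genes tested, the lowest shares kept under the choices fixed beforehand were 82.3% for the Epo effect (without 5 h) and 52.5% for its change (difference of means). They were 80.7% for time without Epo (without 6 h) and 62.2% for the late comparison (without 24 h). From the own 0 h arrays 4 genes were higher and 13 lower with Epo, and 252 and 454 with drift allowed. These fits kept 0.13% and 7.5% of the main calls of the Epo effect, and are less precise than the main fit. Of the named genes of this comparison 48 lost their call from the own 0 h without drift and 2 turned, Stat5b to 0.23 and Mpo to 0.78. The 4 others were Jun, Socs3 and Txnip, still called, and Stat5a, called neither in the main fit nor here, whose sign changed to 0.15. With drift allowed 13 lost their call, the same 2 turned and 39 stayed, Stat5a among them. Of the lists 19 stayed, 6 gained a call, 2 lost one and 4 turned (19, 6, 0 and 6 with drift). Lists whose camera direction turned from the own 0 h, with camera adjusted p first without and then with drift, were JAK2/STAT5 negative regulators (0.0069, 0.0051), receptor pathway components (0.60, 0.54) and granulocyte markers (4.0e-05, 7.8e-06), all to higher, and hepatocyte markers to lower (0.0069, 0.019). With drift, globins also turned to lower (camera adjusted p = 0.016). Progenitor genes turned in camera's direction only, with a median of -0.13 (camera adjusted p = 0.93). For receptor pathway components and progenitor genes this was a lost call, not a call to higher. These lists differed at 0 h between the series, which the subtraction removes by construction. For the change of the Epo effect, leaving out each hour gave 866 to 1329 rising and 863 to 1406 falling genes, from fewer pairs, and the difference of means gave 610 and 929; the cause was not tested. For the late comparison, leaving out each time gave 1830 to 3653 rising genes, the lowest without 24 h, and the brighter genes alone 1776, from fewer genes tested. At a log2 difference of at least 0.58 in place of 1, the hourly counts from 0 to 7 h were 2370, 2234, 4376, 3398, 3887, 5092, 4626 and 4362, and among the brighter genes 356 at 0 h. Without 0 h, the ATF4 and autophagy lists lost their calls in cells without Epo (camera adjusted p = 0.12 and 0.11). The immediate early and ERK feedback list gained a call to lower there (camera adjusted p = 0.00010, from 0.38). A logarithm with an added 1, meant for linear values, was not run, since the values are log2. Signal over background limits dim genes, which were not removed.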

Other observations

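The small nucleolar RNA host gene test was chosen only after the result was seen, and no test was run on the values at 1 h.

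Late under Epo, markers of other blood cells and interferon response genes passed no camera test as lists, while single members changed. Of 12 megakaryocyte markers 5 rose and 0 fell (camera adjusted p = 0.061, and 0.048 without 5 h or 0.033 without 24 h), with Pf4, a platelet chemokine gene, at 2.03 ± 0.23 (log2, SE, n = 3 and 8 arrays) and Gp9 at 0.97 ± 0.21. Of 13 granulocyte markers 6 rose and 3 fell (camera adjusted p = 0.58): the late neutrophil genes S100a8 (2.14 ± 0.23) and S100a9 (1.56 ± 0.26) rose, and the early granule enzyme genes Mpo (-1.51 ± 0.22) and Prtn3 (-1.09 ± 0.17) fell. Of 18 macrophage markers 5 rose and 1 fell (camera adjusted p = 0.13), with Lyz2 at 1.18 ± 0.20. Of 9 mast cell and basophil markers 3 rose and 0 fell (camera adjusted p = 0.28), and of 13 lymphoid markers 2 rose and 0 fell (camera adjusted p = 0.32). Of 22 interferon response genes 6 rose and 2 fell (camera adjusted p = 0.44), the GTPase gene Igtp by 2.92 ± 0.30 and the chemokine gene Cxcl10 at -2.41 ± 0.28.

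Jun and Hspa1a peaked at 1 h in both series; these genes and Txnip were chosen after their values were seen, with 1 array per time. Without Epo, Jun went from 4.94 at 0 h to 10.94 at 1 h and 7.82 at 7 h, and Hspa1a from 5.81 to 11.25 and 5.04. With Epo, Jun went from 6.96 to 8.59 and 5.19, and Hspa1a from 8.86 to 9.19 and 4.66. Txnip went from 7.49 at 0 h to 11.73 at 2 h without Epo, and from 7.58 to 6.53 with it.

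Host genes of small nucleolar RNAs, whose spliced RNAs decay through translation, were hypothesised to accumulate without Epo as ribosome biogenesis genes fell. The median slope of 15 such genes (Gas5 and the Snhg genes) was 0.015 per h, at the 82.6th percentile of 10000 random lists of equally bright genes, and 6 rose and 2 fell. Over all 18194 genes 2432 rose and 2799 fell, and among the brighter 9097 genes 2316 and 2593. The hypothesis was not borne out by the median slope, and the share of host genes that rose was not tested.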
